A study of Homo sapiens with 6 samples.

How the data were processed

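Total RNA of CAL-27 cells was sequenced as single-end reads of 50 bases on a BGISEQ-500 instrument, per the labels' protocols. There were 6 libraries, 3 untreated and 3 treated with ES-Cu for 24 h. The doses were not given in the sources used here.

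The deposited table holds TPM made by the authors, with each library scaled to one fixed total over the listed genes and rounded to 2 decimals. HISAT and Bowtie2 are named in the submitters' processing notes, without versions, and the quantification tool and annotation were not given in the sources used here. Those notes name GRCm38.p6, a mouse build, whereas the table lists human genes. Of its 16809 Entrez identifiers, 16753 (99.7%) were found in the human RefSeq gene table and 16695 of these were protein coding. No coordinates are given for that reason. TPM keeps no read totals, so the depth of each library and the counting error of each value are unknown, and no interval of counting error and no detection limit was computed. The 95% intervals given for medians come from 1000 bootstrap resamples of genes, which are not independent, and do not cover the spread between libraries. An exact 0 is reported as listed at 0.

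The computations started from the deposited TPM. Genes with a mean of at least 1 TPM over the 6 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). All adjusted p-values of single genes come from that limma test unless a setting is named. No block was used for the replicate number. Standard deviations are given over 3 libraries per group. Shares of TPM were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1.

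Before the data were examined, 35 gene lists were written down, and the 32 with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Camera compares a list with the other genes, so a list with a median below 0 can still be called higher. fry asks whether the genes of a list move one way on balance and does not compare them with others; it called 11 lists higher and 18 lower. As a description added after the data were seen, the median log2 fold change of each list was ranked among the medians of 10000 random lists of the same size, drawn to match its members over 20 bins of mean expression. The listed histone genes were matched under their current symbols. The genes named were fixed by rule at the same time. The rule took the 6 higher and 6 lower genes with the largest absolute log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 TPM in a group and no overlap between groups. It added 16 genes of copper handling, cuproptosis, stress and Wnt signalling whatever their values, and up to 3 members of each list with the largest change, a mean of at least 5 TPM in a group and an adjusted p under 0.05. Some genes that the rule takes are not reported here. HSPB1 and FOSL2 fall outside that rule and were named after their values were seen, as exceptions to a count.

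Because TPM sums to a fixed total, a rise of abundant genes lowers all others. Each result was therefore also computed after scaling by the median of ratios and after quantile normalization. The requirement that a gene keep its sign and its call in all 3 scalings before it is said to rise or fall was set after the shift of the median gene had been seen. Other alternatives were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 TPM, removal of the 20 highest genes, limma without the trend, array weights, limma treat with a minimum log2 fold change of 0.5, a replicate block and leaving out each library. Removal of the GC trend of each library was added after the data were seen. Transcript length, GC content and exon number came from GENCODE and were found for 99.4% of tested genes.

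The code was tested on simulated libraries for the comparison of ES-Cu with control, built from 11927 genes with 200 changed. The changed genes and the list members were drawn only from genes whose mean log2(TPM + 1) in control lay above that of 5 TPM. Recovery of tested genes below that level is therefore unknown. A case with most genes changed, as in the real libraries with 9979 called, was not simulated. It recovered 50 of 50 genes changed by -1 and 48 of 50 changed by 1 on the log2 scale, 40 of 50 changed by -0.5 and 37 of 50 changed by 0.5, and called 8 of 11727 unchanged genes. Of 20 lists raised by 0.3, 20 were called, and 0 of 20 unchanged lists were called higher. Genes in these list simulations were drawn independently, without a shift of the median gene, and unchanged lists called lower were not counted. They therefore do not show how often lists of correlated genes are falsely called. In the real libraries a split that mixed both groups gave 19 called lists.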

Results

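CAL-27, a human tongue squamous carcinoma cell line, was profiled by RNA sequencing in 2 groups of 3 libraries. One group was the untreated control and the other had received elesclomol and copper (ES-Cu) for 24 h. Elesclomol is a copper ionophore that carries copper into cells and is used to trigger cuproptosis, a copper-dependent cell death tied to lipoylated mitochondrial enzymes and iron-sulfur proteins. Values were TPM, a share of transcripts corrected for gene length, for 16809 genes, of which 14959 to 15051 lay above 0 in each library. Sequencing depth was unknown, since TPM keeps no read totals. Log2 values of libraries correlated across genes at r = 0.994 to 0.995 within groups and at 0.937 to 0.939 between groups, and the first principal component, which separated the groups, held 92.2% of the variance. Genes are not independent replicates in such a correlation. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

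Per the submitters' description, the comparison of ES-Cu with control addressed gene expression in cuproptosis. Whether the cells died by it was not analysed here. Genes for copper binding, protein folding and oxidative defence were among those with the largest rises. HSPA6, a stress-inducible HSP70 chaperone, went from 1.02 ± 0.141 to 2406 ± 27.0 TPM (mean ± SD, n = 3 per group, as throughout). HMOX1, the haem-degrading enzyme haem oxygenase 1, rose from 13.2 ± 0.533 to 1324 ± 42.6 TPM, and the metallothionein MT1M from 4.58 ± 2.93 to 933 ± 102 TPM. The mitotic kinase gene PLK1 fell (log2 fold change -2.12), as did EGLN3 (-2.84) and IFIT1 (-2.35).

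A total of 9979 of 11927 tested genes differed at an adjusted p under 0.05 (limma-trend, Benjamini-Hochberg), 1628 higher and 8351 lower in ES-Cu. At least 2-fold differences were found for 321 higher and 2167 lower genes. The median gene had a log2 fold change of -0.50 on the deposited scale. After median-of-ratios scaling the median was 0.00 and the split became 4532 higher and 4266 lower, with 836 and 536 genes at 2-fold or more. Quantile normalization gave a median of -0.07 and 3749 higher against 4756 lower genes, and removal of the GC trend of each library gave 4368 higher and 4175 lower. Of the genes called lower on the deposited scale, 1301 were called higher after median scaling. With one sign in all 3 scalings, 1614 genes were higher and 3719 were lower. Counts of list members below are to be read against these numbers out of 11927. Below, a gene is said to rise or fall only if it was called with one sign in all 3 scalings, and fold changes are those of the deposited TPM on the log2(TPM + 1) scale, which understates changes of low genes. For each gene list fixed beforehand, the numbers called on the deposited scale are given adjusted over the list alone. They equalled those adjusted over all genes except in 4 lists, where both are given.

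**Figure D1:**
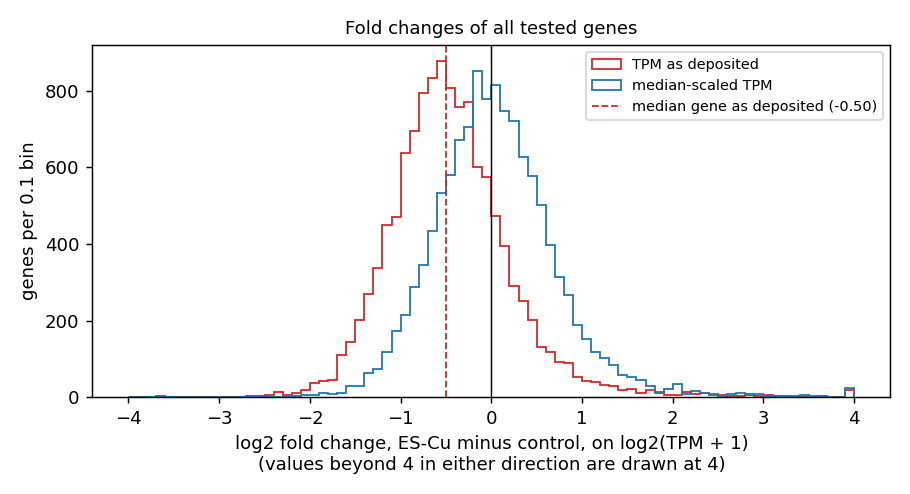
Number of tested genes per 0.1 bin of log2 fold change (ES-Cu minus control, log2(TPM + 1)) for TPM as deposited (red) and after median scaling (blue). The dashed line marks the median gene as deposited, at -0.50, which median scaling moved to 0.00.

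The 6 genes with the largest rise under the naming rule were HSPA6 (log2 fold change 10.22, adjusted p = 3.82e-16, limma-trend), MT1B, MT1M (7.56), the cardiac ankyrin repeat gene ANKRD1 (7.04), the immediate early gene ARC (7.01) and HMOX1 (6.54, adjusted p = 1.21e-15, limma-trend). MT1B was listed at 0 in every control library and at 201, 266 and 192 TPM in the ES-Cu libraries. ANKRD1 rose from 1.93 ± 0.452 to 382 ± 18.7 TPM and ARC from 0.303 ± 0.0808 to 167 ± 5.10 TPM. The 6 largest falls were in SMIM11A (-3.67), DEPP1 (-3.62), TCAF2 (-2.97), EGLN3 (-2.84), the linker histone gene H1-10 (-2.69) and the intermediate filament gene VIM (-2.64). VIM fell from 958 ± 16.1 to 153 ± 3.41 TPM and DEPP1 from 69.0 ± 4.62 to 4.71 ± 0.875 TPM. SMIM11A and TCAF2 have near-identical copies, and their TPM is uncertain for that reason.

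Metallothioneins, which bind copper and zinc, made up most of the list with the largest median change. The list as fixed also held the zinc transporter genes SLC30A1 and SLC30A2, which are not metallothioneins. All 9 tested members of the metallothionein list were called higher over all genes and also when adjusted over the list alone, and 8 rose in all 3 scalings (camera adjusted p = 8.24e-16; adjusted p = 0.0379 with an estimated correlation). MT1X rose from 848 ± 19.8 to 10968 ± 256 TPM (log2 fold change 3.69). MT1H was listed at 0 in the controls and at 46.5, 71.7 and 63.7 TPM in ES-Cu. MT2A, the highest gene of each library, stood at 15354 ± 843 TPM in control and 42875 ± 3074 TPM in ES-Cu (log2 fold change 1.48, and 2.04 after median scaling). Quantile normalization sets the top-ranked gene to one value in all libraries, so MT2A was at 0 there. The list took 1.94% ± 0.0928 of all TPM in control and 7.79% ± 0.461 in ES-Cu (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). MT1 genes are close paralogs, and short reads could be split among them.

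Heat shock genes rose together. Of 24 tested targets of HSF1, the heat shock transcription factor, 21 were called higher and 1 lower, with the same numbers adjusted over the list alone, and 21 rose in all 3 scalings (camera adjusted p = 8.28e-28; adjusted p = 0.0128 with an estimated correlation). HSPA1A went from 310 ± 10.3 to 18265 ± 324 TPM and its near-identical copy HSPA1B from 394 ± 9.06 to 15007 ± 116 TPM. The sum of the list was 1.10% ± 0.00852 of TPM in control and 6.38% ± 0.0607 in ES-Cu (exact permutation p = 0.1). The gene called lower on the deposited scale was HSPB1, at -0.68, which was not called with one sign in all scalings.

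Oxidative defence and amino acid stress genes rose as well. Among 26 tested targets of NRF2, the regulator of antioxidant genes, 20 were called higher and 4 lower (the same numbers adjusted over the list alone), and 19 rose in all 3 scalings (camera adjusted p = 2.49e-17; adjusted p = 0.0128 with an estimated correlation). SLC7A11, the cystine transporter, rose from 3.62 ± 0.280 to 42.2 ± 3.61 TPM and the aldo-keto reductase AKR1C1 from 2.05 ± 0.663 to 25.7 ± 0.866 TPM. Of 26 tested genes of the ATF4 integrated stress response, 18 were called higher and 5 lower, also adjusted over the list alone, and 18 rose and 1 fell in all 3 scalings (camera adjusted p = 8.24e-16; adjusted p = 0.0379 with an estimated correlation). TRIB3, ATF3 and PPP1R15A had log2 fold changes of 3.68, 3.09 and 3.04. The unfolded protein response of the endoplasmic reticulum was mixed, with 7 of 20 members rising and 5 falling in all 3 scalings (7 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0815 towards higher, 0.0472 after median scaling and 0.591 under quantile normalization; adjusted p = 0.376 with an estimated correlation). DNAJB9 (1.71) and HERPUD1 (1.15) rose, and the folding enzyme PDIA4 (-1.10) fell.

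Immediate early and AP-1 genes, which are induced within minutes to hours of a stimulus, were higher as a list. Over all genes and adjusted over the list alone, 19 of 23 were called higher and 1 lower, and all 20 kept that sign in the 3 scalings (camera adjusted p = 9.77e-21; adjusted p = 0.0128 with an estimated correlation). FOSB rose from 0.510 ± 0.217 to 53.3 ± 4.34 TPM, and the phosphatase genes DUSP1 and DUSP5 had log2 fold changes of 3.91 and 2.88. The exception was FOSL2, at -0.99. Inflammatory genes split. Of 23 NF-kB and cytokine genes, 10 rose and 7 fell in all 3 scalings (10 higher and 12 lower adjusted over the list alone). CXCL8 (2.08) and CSF2 (2.06) rose, and the chemokine CCL2 fell from 535 ± 61.2 to 166 ± 3.31 TPM. The call of that list as higher (camera adjusted p = 0.00255; adjusted p = 0.0924 with an estimated correlation) had an adjusted p of 0.0959 under quantile normalization, and its median, -0.16, had the opposite sign of its mean, 0.14.

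Copper transport genes did not pass the test as a list, and the importer gene and one exporter gene changed sign with the scaling. SLC31A1, the high-affinity copper importer, was at 46.9 ± 1.25 TPM in control and 38.8 ± 2.10 TPM in ES-Cu (log2 fold change -0.27, which turned to 0.28 after median scaling and was 0.073, not called, under quantile normalization). The copper exporter ATP7A had a log2 fold change of -0.38, and 0.03 after median scaling, and was called higher under quantile normalization (0.26, adjusted p = 0.0459, limma-trend). ATP7B, the related exporter, fell in all 3 scalings, from 3.22 ± 0.375 to 0.950 ± 0.210 TPM (log2 fold change -1.12, adjusted p = 1.29e-05, limma-trend). Of 16 tested copper transport and chaperone genes, 4 fell and 1 rose in all 3 scalings (1 higher and 12 lower adjusted over the list alone), and camera gave an adjusted p of 0.808. STEAP3 (-1.40), SCO2 (-1.31) and the superoxide dismutase copper chaperone CCS (-0.98) fell.

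Among genes linked to cuproptosis, FDX1, a ferredoxin reported as its key regulator, stood at 7.28 ± 0.403 TPM in control and 5.44 ± 1.33 TPM in ES-Cu. Its log2 fold change was -0.38 as deposited and 0.10 after median scaling, and its call was lost without control replicate 1 (log2 fold change -0.34, adjusted p = 0.0721) and without ES-Cu replicate 3 (-0.21, adjusted p = 0.0944, limma-trend). The log2 fold change of FDX1 was also not called without a low-value filter (adjusted p = 0.0648), with the 20 highest genes removed (-0.25, adjusted p = 0.131), with the GC trend removed (-0.022, adjusted p = 0.898), after median scaling (adjusted p = 0.567) or under quantile normalization (0.23, adjusted p = 0.177, limma-trend). LIAS, the lipoic acid synthase, fell in all 3 scalings, from 23.1 ± 0.595 to 12.1 ± 1.04 TPM. DLAT, a lipoylated subunit of pyruvate dehydrogenase, was at -0.67 as deposited and -0.14 after median scaling, where it was not called (adjusted p = 0.114, limma-trend). In the lipoylation list 7 of 15 genes fell in all 3 scalings and 0 rose (0 higher and 13 lower adjusted over the list alone). Examples were DBT (-1.10), OGDH (-1.04) and NFU1 (-0.97). Camera gave an adjusted p of 0.0578 for this list, and 0.275 with an estimated correlation. The list median, -0.67, lay at percentile 7.45 of random lists matched on mean expression (median -0.44). The list passed the threshold without ES-Cu replicate 1 (adjusted p = 0.0405), under quantile normalization (0.0350), without a low-value filter (0.0105), with a filter of 5 TPM (0.0474) and with the GC trend removed (0.0263), but not after median scaling (0.244).

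Other mitochondrial lists held members that fell, in shares near that of all tested genes (3719 of 11927 fell in all 3 scalings). Of 21 iron-sulfur cluster assembly genes, 7 fell and 2 rose in all 3 scalings (2 higher and 18 lower over all genes, 2 and 19 adjusted over the list alone; camera adjusted p = 0.277), with FDXR (-1.19), NFS1 (-0.96) and NUBP2 (-0.90) among those that fell. Of 19 tricarboxylic acid cycle genes, 5 fell (0 higher and 18 lower adjusted over the list alone), among them IDH2, which went from 131 ± 4.55 to 47.0 ± 0.854 TPM, PC (-1.17) and SUCLG2 (-1.06). The list was called lower (camera adjusted p = 0.00760), but with an adjusted p of 0.119 with an estimated correlation, 0.774 after median scaling and 0.246 with the GC trend removed. Under quantile normalization it was 9.61e-04, also lower, and the list median, -0.56, lay at percentile 2.20 of random lists matched on mean expression (median -0.29). Of 36 nuclear subunits of oxidative phosphorylation, 10 fell and 1 rose in all 3 scalings (1 higher and 33 lower over all genes, 2 and 33 adjusted over the list alone), with ATP5F1A (-0.87) and NDUFA2 (-0.85) as examples. Its call (camera adjusted p = 0.0149; adjusted p = 0.0924 with an estimated correlation) turned direction after median scaling (adjusted p = 0.698), but was kept, towards lower, under quantile normalization (adjusted p = 8.08e-05). The call was also lost without the trend (0.0690), with the 20 highest genes removed (0.0701) and with the GC trend removed (0.846). Among random lists matched on mean expression (median -0.23) the list median, -0.49, lay at percentile 0.29. None of the 13 mitochondrially encoded mRNAs was analysed here.

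**Figure D2:**
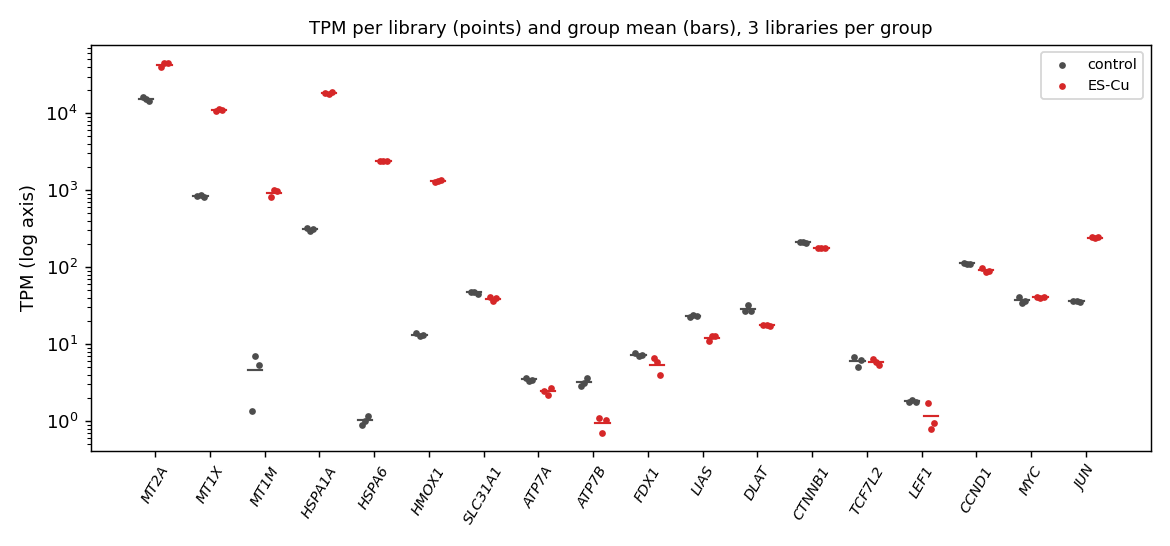
TPM on a log axis of copper, stress, cuproptosis and Wnt genes in each library (points; dark, control; red, ES-Cu), with bars at the group means of 3 libraries. MT1X went from 848 to 10968 TPM, whereas the difference of SLC31A1, CTNNB1 and CCND1 turned from lower to higher after median scaling.

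The title the submitters gave the series names Wnt signalling, a pathway in which beta-catenin activates transcription with TCF and LEF factors. The labels name no alteration of that pathway in these libraries. CTNNB1, which encodes beta-catenin, was at 210 ± 3.28 TPM in control and 177 ± 1.55 TPM in ES-Cu, a log2 fold change of -0.25 that turned to 0.31 after median scaling and was -0.085, not called, under quantile normalization. TCF7L2 did not pass the test as deposited (log2 fold change -0.03, adjusted p = 0.793, limma-trend) but was called higher after median scaling (0.44, adjusted p = 0.00452) and under quantile normalization (0.58, adjusted p = 9.56e-04, limma-trend). LEF1 was at 1.81 ± 0.0404 TPM in control and 1.15 ± 0.480 TPM in ES-Cu, and its call (log2 fold change -0.41, and -0.08 after median scaling) was lost when any one of control replicates 1, 2 and 3 or ES-Cu replicates 2 and 3 was left out, with adjusted p-values of 0.0617, 0.0781, 0.0648, 0.137 and 0.103 (limma-trend). MYC was at 37.1 ± 3.07 and 40.6 ± 0.481 TPM (log2 fold change 0.13, adjusted p = 0.0737, limma-trend; log2 fold change 0.19, adjusted p = 0.0125 without control replicate 1). It was called higher after median scaling (log2 fold change 0.67, adjusted p = 5.93e-06) and under quantile normalization (0.49, adjusted p = 7.07e-05, limma-trend). CCND1, which encodes cyclin D1, had a log2 fold change of -0.29 that turned to 0.26 after median scaling and was -0.03, not called, under quantile normalization (adjusted p = 0.502, limma-trend). The feedback gene AXIN2, at 0.10 ± 0.0866 and 0.177 ± 0.0493 TPM, lay below the minimum for testing.

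Of 23 tested Wnt target genes, 8 rose and 6 fell in all 3 scalings (8 higher and 12 lower adjusted over the list alone). The members with the largest change were JUN, from 36.0 ± 0.461 to 242 ± 5.36 TPM, FOSL1 (2.17) and PLAUR (1.49). JUN and FOSL1 encode AP-1 factors and PLAUR the urokinase receptor. The list was called higher (camera adjusted p = 0.00491). That call was lost with an estimated correlation (adjusted p = 0.239), after median scaling (0.220), under quantile normalization (0.0583) and with the GC trend removed (0.0710). The list median, -0.29, was below 0 but lay 0.21 above the median gene. Of 20 tested Wnt ligands and receptors, 11 fell and 1 rose in all 3 scalings (1 higher and 19 lower adjusted over the list alone; camera adjusted p = 0.109, towards lower, 0.0345 after median scaling, 0.148 under quantile normalization and 0.0461 with the GC trend removed; adjusted p = 0.471 with an estimated correlation). The median of that list, -0.72, lay at percentile 23.5 of random lists matched on mean expression (median -0.61). FZD2, a Frizzled receptor, fell from 11.4 ± 0.220 to 1.94 ± 0.0700 TPM. The co-receptor LRP5 had a log2 fold change of -1.29 and the R-spondin receptor LGR4 of -0.85. Of 29 intracellular components, 6 rose and 6 fell in all 3 scalings (6 higher and 13 lower over all genes, 5 and 12 adjusted over the list alone). The largest changes were falls of TCF7L1 (-1.33) and the co-repressor genes TLE1 (-1.18) and TLE5 (-0.90). That list had a camera adjusted p of 0.0578, towards higher, 0.0190 after median scaling and 0.0206 under quantile normalization. It also passed without ES-Cu replicate 2 (0.0287), without the trend (0.0462), with the 20 highest genes removed (0.0196) and with the GC trend removed (0.00384). With an estimated correlation its adjusted p was 0.441.

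Mitotic genes fell. All 26 G2/M genes were called lower, also adjusted over the list alone, and all 26 fell in the 3 scalings (camera adjusted p = 6.14e-07; adjusted p = 0.101 with an estimated correlation). KIF20A, a mitotic kinesin, went from 72.7 ± 0.357 to 10.9 ± 0.690 TPM, the kinase PLK1 from 144 ± 1.28 to 32.4 ± 0.361 TPM, and CENPA had a log2 fold change of -1.81. Of 29 DNA replication and S phase genes, 12 fell and 3 rose in all 3 scalings (3 higher and 23 lower adjusted over the list alone; camera adjusted p = 0.151, towards lower, and 0.0175 without a low-value filter; adjusted p = 0.376 with an estimated correlation), with MCM6 (-1.26), POLD1 (-1.19) and MCM3 (-1.07) as examples. Replication-dependent histone genes were higher as a list. Of 19 tested, 11 rose and 1 fell in all 3 scalings, also the counts adjusted over the list alone (camera adjusted p = 2.70e-09; adjusted p = 0.0379 with an estimated correlation), with H2AC18 (2.58), H2BC8 (2.50) and H2BC12 (2.43) as examples. Histone genes are near-identical, so single values are uncertain.

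Most interferon and hypoxia genes tested fell. Of 24 tested type I interferon response genes, 18 fell and 0 rose in all 3 scalings (0 higher and 21 lower adjusted over the list alone; camera adjusted p = 0.00760; adjusted p = 0.0924 with an estimated correlation). IFIT1 went from 11.4 ± 1.62 to 1.43 ± 0.205 TPM, OASL had a log2 fold change of -1.85 and OAS1 of -1.69. Of 27 tested hypoxia and glycolysis genes, 18 fell and 1 rose in all 3 scalings (1 higher and 25 lower adjusted over the list alone; camera adjusted p = 3.38e-04; adjusted p = 0.133 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, went from 76.7 ± 0.661 to 9.86 ± 0.726 TPM, BNIP3 from 264 ± 1.49 to 68.2 ± 2.91 TPM, and ANKRD37 had a log2 fold change of -2.48.

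Protein turnover genes rose in part. Of 31 proteasome subunits, 13 rose and 0 fell in all 3 scalings (13 higher and 5 lower adjusted over the list alone; camera adjusted p = 2.12e-08; adjusted p = 0.0208 with an estimated correlation), with PSMD12 (1.22), PSMC4 (0.84) and PSMD1 (0.63) as examples. After median scaling, which lifted the ES-Cu values, 30 of the 31 proteasome subunits were called higher and 0 lower. Of 28 autophagy and lysosome genes, 11 rose and 2 fell (11 higher and 12 lower adjusted over the list alone). Camera gave this list an adjusted p of 3.04e-04 towards higher, and 0.0379 with an estimated correlation. The list median was -0.07, which lay 0.43 above the median gene. MAP1LC3B rose from 58.8 ± 0.888 to 303 ± 9.61 TPM, the autophagy receptor gene SQSTM1 had a log2 fold change of 1.73 and GABARAPL1 of 1.06. Of 18 ferroptosis regulators, 9 rose and 3 fell (10 higher and 5 lower adjusted over the list alone; camera adjusted p = 2.88e-05; adjusted p = 0.0379 with an estimated correlation). SLC7A11 (3.22) and CHAC1 (2.81) rose and ALOX5 (-1.66) fell. SLC7A11, FTH1 and FTL are also members of the NRF2 list and CHAC1 of the ATF4 list. The call of the ferroptosis list is therefore not independent of theirs. Of 31 ribosome biogenesis genes, 10 rose and 2 fell (10 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.00271 towards higher, with a list median of -0.07; adjusted p = 0.227 with an estimated correlation). NOP58 (0.80) rose, and UBTF (-1.25) and WDR12 (-0.76) fell. Of 63 cytosolic ribosomal protein genes, 5 rose and 0 fell in all 3 scalings (13 higher and 19 lower over all genes, 10 and 16 adjusted over the list alone). That list had a camera adjusted p of 0.00115 towards higher and 0.0379 with an estimated correlation. Its median log2 fold change, -0.04, lay 0.46 above the median gene. After median scaling 61 of the ribosomal protein genes were called higher and 0 lower (camera adjusted p = 1.96e-12, towards higher). The direction of the list turned, however, under quantile normalization (camera adjusted p = 0.0510). RPL32 (-0.60), RPL15 (-0.49) and RPS15 (-0.36) were lower as deposited, and RPL15 and RPS15 turned to 0.06 and 0.19 after median scaling. Ribosomal proteins took 18.1% ± 0.0342 of TPM in control and 17.5% ± 0.181 in ES-Cu (exact permutation p = 0.1).

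Death and p53 genes went both ways. Of 24 apoptosis regulators, 8 rose and 6 fell in all 3 scalings (8 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.0339 towards higher, with a list median of -0.24; adjusted p = 0.227 with an estimated correlation). The pro-apoptotic genes BMF (-1.94), CASP9 (-1.26) and BCL2L11 (-1.25) fell. Of 24 p53 targets, 8 rose and 8 fell (8 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.0309 towards higher, with a list median of -0.40; adjusted p = 0.119 with an estimated correlation). PLK3 and GADD45A both rose by 2.34 on the log2 scale, and the DNA repair gene DDB2 fell (-1.99). The calls of the apoptosis and p53 lists were lost after median scaling (adjusted p = 0.10 and 0.479), under quantile normalization (0.101 and 0.148), with the GC trend removed (0.152 and 0.435), without a low-value filter (both 0.113) and with the 20 highest genes removed (0.0514 and 0.0768).

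Epithelial identity genes were mixed. TP63, the basal keratinocyte factor, fell from 86.8 ± 1.34 to 24.5 ± 0.922 TPM, and the cadherin genes CDH3 (-1.32) and CDH1 (-1.27) fell. Of 16 basal epithelial markers, 8 fell and 3 rose in all 3 scalings (3 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.931), and the list median, -0.62, lay at percentile 1.49 of random lists matched on mean expression (median -0.31). Of 16 keratinocyte differentiation genes, 4 rose and 1 fell (4 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0578, towards higher; adjusted p = 0.227 with an estimated correlation). S100A7 (1.09) and DSC2 (0.75) rose and CNFN (-1.39) fell. The keratinocyte list passed the threshold without control replicate 2 (adjusted p = 0.0198), without ES-Cu replicate 1 (0.0405), without a low-value filter (0.0175) and with a filter of 5 TPM (0.0373). Of 18 mesenchymal genes, 5 rose and 7 fell (5 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.601), with the collagenase MMP1 (2.90) and MMP10 (2.30) against VIM. Of 24 cholesterol synthesis genes, 5 rose and 5 fell (5 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.909). INSIG1 (2.41) rose and MVK (-1.83) fell.

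Few markers of other cell types reached the minimum for testing. Of the fibroblast and smooth muscle markers 4 were tested, of which 1 rose and 2 fell in all 3 scalings (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.931), with ACTA2 at 8.67 ± 0.792 and 2.96 ± 0.875 TPM and COL1A1 at 8.36 ± 0.362 and 3.62 ± 0.269 TPM. The blood list had 1 tested gene, CD68, at 63.6 ± 3.65 and 50.9 ± 2.68 TPM, called lower over all genes and adjusted over the list alone (log2 fold change -0.32, and 0.23 after median scaling). The endothelial list had 2, both called lower adjusted over the list alone, CDH5 (-1.73), which fell in all 3 scalings, and EGFL7 (-0.81), which was not called under quantile normalization.

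**Figure D3:**
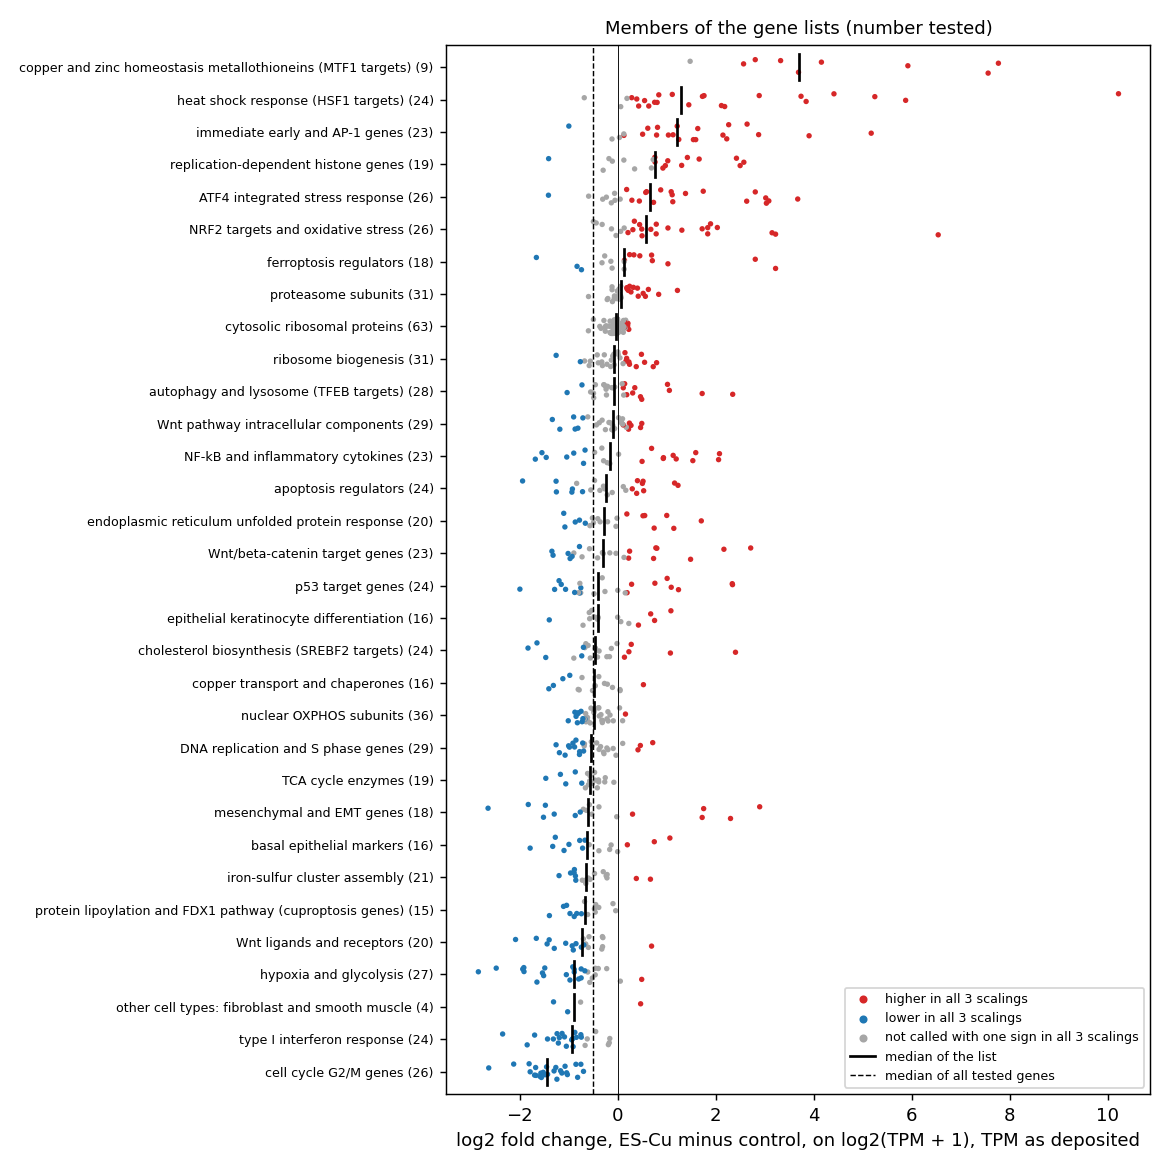
Log2 fold changes of the tested members of 32 gene lists (points), with the list median (bar) and the median of all tested genes (dashed line, -0.50). Red and blue points were called with one sign in all 3 scalings; all 26 G2/M genes are blue, and 8 of 9 metallothionein list genes are red.

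Across the 32 lists tested, camera called 15 higher and 5 lower on the deposited scale. With an estimated correlation 10 were called higher and 0 lower. In all 3 scalings 10 were called higher and 3 lower, the latter being the G2/M, interferon and hypoxia lists. Some lists share members, such as SQSTM1 in the NRF2 and autophagy lists, so the calls are not independent of each other. At the preset correlation a split of the libraries that mixed both groups gave 19 called lists, close to the 20 of the real split. The median log2 fold change of all genes ran from -0.70 in the lowest quartile of mean expression to -0.29 in the highest (-0.31 to 0.26 after median scaling), whereas camera compares a list with genes of all levels. Among 10000 random lists matched on mean expression, the medians of the G2/M and hypoxia lists lay at percentile 0 and that of the interferon list at 0.15. Of the lists called higher, the ribosomal protein list lay at percentile 98.0, apoptosis at 95.9, NF-kB at 95.8, Wnt targets at 89.0 and p53 targets at 80.7, and the others lay above 99. The Wnt component list, not called, lay at 99.6. The 20 highest genes of each library took 14.4% ± 0.157 of TPM in control and 22.2% ± 0.490 in ES-Cu (exact permutation p = 0.1). They were ranked within each library, whereas the 20 genes removed as an alternative were ranked by mean TPM over the 6 libraries.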

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

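The alternatives were fixed before the data were examined, except removal of the GC trend, which was added afterwards. Median scaling, removal of the GC trend and quantile normalization moved the most results. Of 109 alternative values of the gene and list counts, 93 lay within 1.5 times the reported count, as did 952 of 1086 counts of list members. Of 1961 values of named genes 1909 kept their direction and their side of the threshold, and of 607 list tests 535 did. The count of called genes ranged from 9622 to 9816 when one library was left out, with 1493 to 1590 higher and 8070 to 8323 lower. Depth was unknown and sets no stated limit. With treat, which asks for a log2 fold change beyond 0.5, 4796 genes were called, 572 higher and 4224 lower. With an estimated correlation camera called 10 lists, and the Wnt target list had an adjusted p of 0.239.

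After median scaling 4532 genes were higher and 4266 lower, with 836 and 536 at 2-fold or more. The log2 fold change turned sign for SLC31A1 (0.28), ATP7A (0.031), FDX1 (0.10), CTNNB1 (0.31), TCF7L2 (0.44), CCND1 (0.26), RPL15 (0.064), RPS15 (0.19) and CD68 (0.23). The direction turned for the oxidative phosphorylation list (adjusted p = 0.698) and the mesenchymal list (0.774). The Wnt target list lost its call (0.220), and the Wnt ligand and receptor (0.0345), Wnt component (0.0190) and unfolded protein response (0.0472) lists passed the threshold. The TCA cycle (0.774), p53 (0.479) and apoptosis (0.10) lists lost theirs. The turned signs of genes and the split of higher against lower genes follow from the construction of the scaling, which lifted the ES-Cu values. For the lists the cause was not tested.

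Quantile normalization gave 3749 higher and 4756 lower genes, with 684 and 450 at 2-fold or more. The sign turned for SLC31A1 (0.073), ATP7A (0.26), FDX1 (0.23), TCF7L2 (0.58) and LEF1 (0.12), and MT2A was 0 by construction. The ribosomal protein (adjusted p = 0.0510) and mesenchymal (0.740) lists turned direction. The lipoylation list (0.0350) and the Wnt component list (0.0206) passed the threshold, and the Wnt target (0.0583), NF-kB (0.0959), p53 (0.148) and apoptosis (0.101) lists lost their calls.

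With the GC trend removed, which also centres each library, 4368 genes were higher and 4175 lower, with 777 and 401 at 2-fold or more. The sign turned for SLC31A1 (0.12), CTNNB1 (0.18), TCF7L2 (0.43), LEF1 (0.058), CCND1 (0.32), RPL15 (0.0024), RPS15 (0.34) and CD68 (0.26), and the direction of the mesenchymal list (adjusted p = 0.678). The lipoylation (0.0263), Wnt ligand and receptor (0.0461) and Wnt component (0.00384) lists passed the threshold, and the Wnt target (0.0710), TCA cycle (0.246), oxidative phosphorylation (0.846), p53 (0.435) and apoptosis (0.152) lists lost their calls. With the 20 highest genes removed, TCF7L2 was at 0.11, the Wnt component list passed (0.0196), and the oxidative phosphorylation (0.0701), p53 (0.0768) and apoptosis (0.0514) lists lost their calls.

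Without a low-value filter the lipoylation (adjusted p = 0.0105, lower), DNA replication (0.0175, lower) and keratinocyte (0.0175, higher) lists passed, the cholesterol (0.615) and fibroblast (0.983) lists turned direction, and the p53 and apoptosis lists lost their calls (both 0.113). With a filter of 5 TPM the lipoylation (0.0474) and keratinocyte (0.0373) lists passed. Without the trend the Wnt component list was at 0.0462, the basal list turned direction (0.912) and the oxidative phosphorylation list lost its call (0.0690). The causes of these changes, and of those under quantile normalization and GC removal, were not tested. With one library left out, the lipoylation list ranged from 0.0405 (without ES-Cu replicate 1) to 0.0712, the Wnt component list from 0.0287 (without ES-Cu replicate 2) to 0.0881, and TCF7L2 from -0.14 (without control replicate 2) to 0.044 (without control replicate 1).

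fry, which does not compare a list with other genes and so follows the shift of the median gene, gave adjusted p-values of 1.85e-05 for copper transport, 3.85e-05 for lipoylation and 3.77e-05 for Wnt ligands and receptors, all lower. It had the opposite direction of camera for Wnt components (0.00248), the unfolded protein response (0.00471), p53 targets (0.303), ribosomal proteins (0.00112), cholesterol synthesis (7.56e-05), keratinocyte differentiation (0.231), mesenchymal genes (1.48e-04), apoptosis (0.00390) and ribosome biogenesis (0.264).

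The groups share replicate numbers. No sign that the numbers pair the libraries was found, though 3 libraries per group can hardly exclude it. Correlations of the deviations from the group means were 0.0206, -0.0337 and 0.0107 for numbers 1, 2 and 3, and 2 of 6 libraries correlated best with their own number. With the number as a replicate block 9957 genes were called, 1614 higher and 8343 lower, and 20 lists.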

Other observations

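Several genes outside the fixed lists moved with the groups. The following genes were chosen after their values were seen, and all kept their sign and call in the 3 scalings. UBB, which encodes ubiquitin, rose from 2904 ± 149 to 8703 ± 186 TPM (mean ± SD, n = 3 per group; limma-trend adjusted p = 1.94e-10). ZFAND2A, an arsenite-inducible gene linked to the proteasome, rose from 49.1 ± 8.37 to 1535 ± 21.8 TPM and the cochaperone gene DNAJA4 from 21.4 ± 0.990 to 518 ± 10.03 TPM. The cytokine genes IL11 and CLCF1 rose, IL11 from 3.88 ± 0.141 to 90.0 ± 4.95 TPM and CLCF1 from 7.08 ± 0.825 to 38.9 ± 2.23 TPM, and the growth factor gene HBEGF rose from 24.7 ± 0.439 to 174 ± 1.25 TPM. IGFBP3 fell from 281 ± 4.82 to 53.5 ± 1.31 TPM, the hypoxia-inducible lipid droplet gene HILPDA from 51.1 ± 4.04 to 8.80 ± 0.863 TPM, and SMO, the Hedgehog signal transducer, from 58.9 ± 2.65 to 9.98 ± 1.17 TPM.

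The tests of S phase, of the summed histone TPM and of the Wnt feedback genes were chosen after the result, or values that foretold it, had been seen; those of abundant genes, length, GC content, intron-less genes and splits were written before.

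The median gene lay at -0.50 on the deposited scale, with medians from -0.70 in the lowest quartile of mean expression to -0.29 in the highest (-0.31 to 0.26 after median scaling), a gradient whose cause was not tested. The 20 genes with the highest mean TPM do not account for all of the shift of the median. With them removed it was still -0.36 (95% bootstrap interval -0.38 to -0.35). They were chosen by level and not by gain, and the 20 largest gains held 69.7% of the 181916 TPM gained. Removal of the genes that gained most was not tested, so a larger part for them stays open. Transcript length is argued against, as the shortest and longest quartiles differed by -0.031 (-0.07 to 0.00). GC content may contribute and cannot be told apart from the treatment, because the lowest GC quartile lay 0.33 (0.30 to 0.37) above the highest, between the bounds set for and against it. A fall of mRNA per cell that is equal for all genes would leave TPM unchanged and so cannot account for the shift. A fall that differs between genes is open, since TPM does not measure total mRNA.

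Of 19 replication-dependent histone genes 11 rose and 1 fell in all 3 scalings, whereas all 26 G2/M genes fell, a list with an adjusted p of 0.101 with an estimated correlation (camera). Reads moved among the listed near-identical copies are argued against, because the summed TPM of those copies went from 148 ± 7.26 to 431 ± 16.0. In that sum the lowest ES-Cu library lay 35.6 control SDs above the highest control library. Reads moved from copies outside the list would raise the sum as well, so that case stays open. A general rise of genes without introns is argued against by a difference of -0.025 between 206 single-exon and 10904 multi-exon genes outside the lists. Its interval, -0.14 to 0.15, reaches past the bound of 0.1 that had been set against this explanation, and the reading rests on the 0.3 it needed, a reading adopted after the interval was seen. More cells in S phase could also raise histone mRNA. The S phase list lay -0.032 (-0.27 to 0.22) from the median gene. That median met the bound set against this explanation, at most 0.1 above the median gene. The explanation is left open only because the interval reaches past 0.1, a condition that the bound as written did not hold. Camera also called that list lower without a low-value filter (adjusted p = 0.0175, against 0.151 with it). Its median lay at percentile 5.92 of random lists matched on expression.

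The Wnt target list was called higher (camera adjusted p = 0.00491), but that call was lost with an estimated correlation (0.239), after median scaling (0.220), under quantile normalization (0.0583) and with the GC trend removed (0.0710), and the list median lay at percentile 89.0 of random lists matched on expression. A candidate explanation is that members which are also AP-1 or growth factor response genes, such as JUN and FOSL1, carry the call. In line with this, the 6 tested of 12 feedback genes, which include LEF1, had a median log2 fold change of -0.65, against 0.13 for the other 17 targets and -0.50 for all tested genes, and so lay -0.15 (-0.64 to 0.14) from the median gene. That interval includes 0 and the genes were picked after the list was seen, so this remains a hypothesis.

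The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 9979 genes and was the 1 split with as many, and the highest other split gave 0 genes. Every other split mixes control and ES-Cu libraries, so the treatment difference widens the spread within its groups. Calls of genes were hardly possible there, and the 0 is not evidence about the real split. For gene lists the real split gave 20 and was again the 1 split with as many, but another split gave 19. A mixed split still holds part of the treatment difference, so it is no case without change. The count of lists called at the preset correlation is weak support by itself.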
